A study of Homo sapiens with 6 samples.

How the data were processed

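RNA was measured in 6 libraries of HT-29 cells, an established human colorectal adenocarcinoma line. The series compares control cells with cells in which CUL4A was knocked down, in triplicate. Per the labels' protocols, cells were flash frozen, RNA was extracted with Trizol, and libraries were built from total RNA with an Illumina TruSeq RNA kit. Neither how CUL4A was knocked down nor what the control cells received is given in the sources used here. Libraries were grouped by the codes W1 to W3 and K1 to K3 in their descriptions, read as control and knockdown because the series names only these groups, in triplicate. That reading rests on the codes, and the CUL4A level in each library was checked against it. Nothing in the labels says that the 3 libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

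The authors deposited one table of TPM values (transcript abundance scaled for gene length and library total) for 63241 human Ensembl gene identifiers, of which 42640 had a gene symbol. In each deposited column TPM summed to about 1e+06, with 2 decimals kept, so sequencing depth is unknown and no count model or counting interval could be used. The aligner and the quantification tool are not given in the sources used here. The genome build named per the submitters' processing notes is mm8, a mouse build, while the gene identifiers are human, so the build the authors used is left open. Coordinates and gene types were therefore taken from GENCODE release 29 on GRCh38 by gene identifier, which matched 58228 identifiers and 13492 (96.5%) of the genes tested. Whether reads were assigned by strand is not given in the sources used here, so genes overlapping another gene, antisense genes and members of near-identical families cannot be fully separated.

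Genes with at least 1 TPM in at least 3 of the 6 libraries were kept, which left 13975. Values were transformed to log2(TPM + 1), a scale that understates the change of low genes, and no further scaling was applied. The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend), two-sided, with Benjamini-Hochberg adjustment over all genes kept and a threshold of 0.05. Every adjusted p given for a gene is from this limma fit, and every fold change is knockdown relative to control on the log2(TPM + 1) scale. Means of TPM are given ± SD over 3 libraries. Single measures were compared by an exact permutation test, two-sided, which with 3 against 3 libraries cannot give a p below 0.1.

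Before the data were examined, 27 gene lists were fixed, together with the test, the alternatives and the rule for naming genes. The 25 lists with at least 5 genes kept were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists. Each was tested again with the correlation estimated from the residuals, and with limma's fry, which asks whether the genes of a list move one way and makes no comparison with other genes. Per list, members were also counted with p-values adjusted over the list alone. Genes named were CUL4A, the 10 largest changes in each direction, and up to 4 called members of each list with the smallest adjusted p. For a list with no called member, up to 2 with the highest mean TPM could be named. The 10 per direction had to be protein coding, with a mean of at least 5 TPM in the higher group and no overlap between groups. The table holds no gene type, so the GENCODE type was used for this. Some genes that the rule takes are not reported here. Any gene named outside the rule is said to have been chosen after its values were seen. No column of other samples was in use.

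On simulated data 200 of 13975 genes were changed, and 13335 genes passed the filter. Among these the test of control against knockdown recovered 27.3% of changes of 0.5 on the log2 scale. It recovered 80.3% of changes of 1 and 100% of changes of 2, and called 5 unchanged genes. Far fewer genes were changed than were called in the data, which makes the adjusted threshold stricter, so these shares do not carry over to the data. In a simulation without changes, limma called 0 genes and camera 0 lists. Simulated genes varied independently, so this cannot show how camera behaves when the genes of a list vary together. The alternatives were other pseudocounts (0.1 and 5), no filter or a mean of at least 5 TPM, median-ratio scaling, quantile normalization, protein-coding genes only, rescaling without mitochondrial-encoded and the 20 most abundant genes, robust eBayes, array weights, a replicate block, a minimum absolute log2 fold change of 1, and leaving out each library. Removal of a trend with GC content and transcript length, and a test of the KEGG pathways assigned in the deposited table, were added after the data were seen. Figures were drawn with matplotlib.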

Results

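The transcriptome of HT-29 colorectal cancer cells was compared between control cells and cells with CUL4A knocked down, 3 libraries each. CUL4A is a scaffold of the CRL4 ubiquitin ligases, which act in DNA replication, DNA repair and the cell cycle. The question was how messenger RNA levels differ after loss of CUL4A. Depth is unknown, because the deposited values are TPM. Between 23153 and 24962 genes had a value above 0 in a library. The mean number was 23545 ± 449 in control and 24732 ± 320 after knockdown (SD, exact permutation p = 0.1, the smallest that 3 against 3 libraries allow). Mitochondrial-encoded genes held 39.8 ± 2.41% of TPM in control and 35.4 ± 3.09% after knockdown (SD, exact permutation p = 0.1). The first principal component separated the groups and held 65.4% of the variance. The second, with 12.03%, mainly separated control replicate 2 from control replicate 3.

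CUL4A messenger RNA fell from 63.7 ± 4.06 TPM in control to 24.5 ± 1.29 TPM after knockdown, to 38.4% of the control level. CUL4A (ENSG00000139842) lies on chromosome 13 from 113208193 to 113267108 on GRCh38. Its values were 67.0, 59.2 and 65.0 TPM in the control libraries and 25.5, 24.9 and 23.1 TPM in the knockdown libraries. The log2 fold change was -1.34 (SE 0.09, limma adjusted p = 1.9e-05), lower in every knockdown library than in any control library. CUL4B, the paralog of CUL4A, was at 14.4 ± 1.85 TPM in control and 11.6 ± 0.28 TPM after knockdown, and did not pass the threshold (limma adjusted p = 0.0832). CUL4B was nonetheless lower in every knockdown library than in any control library, and its lack of a call did not hold in every alternative. It was chosen after its values were seen.

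**Figure D1:**
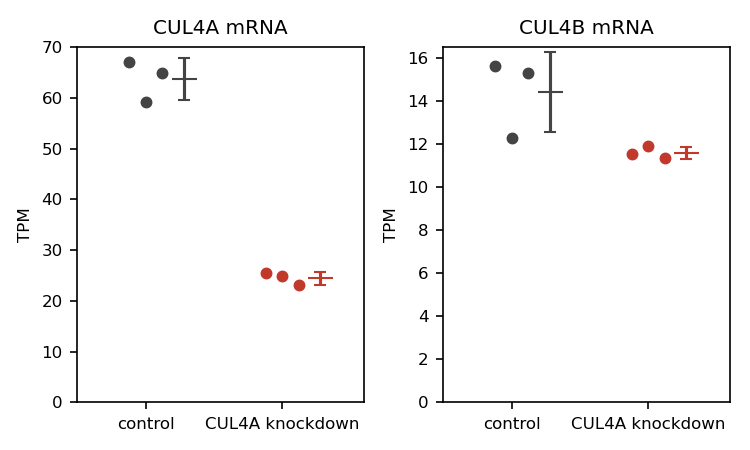
TPM of CUL4A (left) and CUL4B (right) in each of the 3 control and 3 knockdown libraries. Points are libraries, and the bars beside them show the mean ± SD. CUL4A lies between 23.1 and 25.5 TPM in the knockdown libraries, below all control libraries. CUL4B lies between 11.4 and 11.9 TPM in the knockdown libraries, also below all control libraries, the lowest of which is at 12.3 TPM.

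Among 30 measured components and regulators of CRL4 ligases, 2 rose, 3 fell and 25 did not pass the threshold. Adjusted over the list alone, 0 rose and 3 fell. DTL, the substrate receptor that targets CDT1 for degradation, fell from 8.69 ± 2.23 to 3.33 ± 0.462 TPM. CAND1, the exchange factor for cullin substrate receptors, fell from 28.5 ± 3.6 to 19.8 ± 1.23 TPM, and NAE1, a subunit of the NEDD8-activating enzyme, from 30.6 ± 4.88 to 21.9 ± 0.398 TPM. The 2 that rose were DCAF7 (log2 fold change 0.27) and AMBRA1 (0.33), the latter chosen after its values were seen. The calls of NAE1, DCAF7 and AMBRA1 did not hold in every alternative. The list as a group did not pass (camera adjusted p = 0.14, and 0.653 with an estimated correlation), but passed without a filter (0.0331). Of 7 other cullins, CUL1 fell from 19.97 ± 2.4 to 13.6 ± 1.35 TPM and CUL2 fell to 8.93 ± 0.534 TPM (log2 fold change -0.38), with CUL2 not called in every alternative. Adjusted over the list alone, 1 rose and 2 fell, and the group did not pass (camera adjusted p = 0.463, and 0.653 with an estimated correlation).

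Across 13975 genes tested, 2637 (18.9%) rose and 2368 (16.9%) fell after knockdown at a limma adjusted p below 0.05. The larger changes were mostly increases: 558 genes rose and 174 fell by at least 1 on the log2 scale. The filter could take a gene through the libraries of either group alone, and more genes reached 1 TPM after knockdown. Their mean number was 14008 ± 135 (SD), against 13570 ± 139 in control. With a mean of at least 5 TPM required, 1788 genes were higher and 1990 lower (47.3% higher). The 3 knockdown libraries lay wholly on one side of the 3 control libraries for 6900 genes (49.4%, where chance gives 10%). Higher genes made up 52.7% of calls with TPM as deposited, and 40.5% (2374 higher, 3490 lower) with TPM rescaled without mitochondrial-encoded and the 20 most abundant genes. Array weights gave 3227 higher and 3857 lower genes (45.6% higher), and no filter gave 2185 higher and 1536 lower. Counts of higher genes were 1576 without knockdown replicate 1 and 1729 without knockdown replicate 2. Counts of lower genes were 1425 without control replicate 1, 1547 without knockdown replicate 2 and 1569 without knockdown replicate 3.

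The largest increases included genes known to respond to low oxygen. NDUFA4L2, a mitochondrial protein of hypoxic cells, rose from 0.407 ± 0.256 to 50.8 ± 2.59 TPM (log2 fold change 5.22, SE 0.14, limma adjusted p = 1.15e-07; chromosome 12, 57234903 to 57240715 on GRCh38). CA9, a cell surface carbonic anhydrase, rose from 11.7 ± 1.64 to 217 ± 20.1 TPM (log2 fold change 4.11, SE 0.12, limma adjusted p = 1.16e-07; chromosome 9, 35673856 to 35681159). The glycolytic aldolase ALDOC rose from 4.18 ± 0.0961 to 65.7 ± 6.34 TPM and NDRG1 from 20.9 ± 1.25 to 251 ± 22 TPM. The insulin-like growth factor binding protein IGFBP2 rose from 1.77 ± 0.527 to 41.9 ± 1.71 TPM. IFITM1, an interferon-induced membrane protein with close paralogs, rose from 37.3 ± 1.06 to 372 ± 21.3 TPM. The trypsin inhibitor SPINK1 rose from 4.56 ± 1.84 to 44.6 ± 5.67 TPM and ceruloplasmin (CP), a copper-binding ferroxidase, from 1.06 ± 0.612 to 15.9 ± 0.934 TPM. The nucleoside and monoamine transporter SLC29A4 rose from 1.37 ± 0.238 to 17.6 ± 2.11 TPM, and the chemokine CCL15 from 3.10 ± 1.36 to 28.1 ± 0.416 TPM.

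The largest decrease under the naming rule was that of EGR1, an immediate-early transcription factor, which fell from 55.4 ± 2.65 to 6.76 ± 0.242 TPM (log2 fold change -2.86, SE 0.09, limma adjusted p = 2.46e-07; chromosome 5, 138465490 to 138469315 on GRCh38). HBEGF, a ligand of the EGF receptor, fell from 11.8 ± 0.68 to 1.21 ± 0.155 TPM (log2 fold change -2.53, SE 0.12, limma adjusted p = 2.62e-06). ERRFI1, a feedback inhibitor of that receptor, fell from 191 ± 17.9 to 51.1 ± 1.19 TPM, and FOSL1, an AP-1 subunit, from 31.7 ± 3.16 to 8.9 ± 2.24 TPM. The neutrophil chemokine CXCL8 fell from 252 ± 80.5 to 62.8 ± 4.29 TPM, CXCL3 from 126 ± 21.9 to 35.8 ± 4.54 TPM and CCL4 from 6.39 ± 1.09 to 0.98 ± 0.07 TPM. Interferon beta (IFNB1) fell from 56.4 ± 9.62 to 15.4 ± 1.98 TPM. The trypsinogen PRSS2 fell from 156 ± 4.72 to 39.0 ± 3.07 TPM and the collagen COL8A1 from 7.50 ± 0.52 to 1.66 ± 0.147 TPM. PRSS2, CCL4 and CXCL3 have near-identical relatives, so their values are uncertain to that extent.

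**Figure D2:**
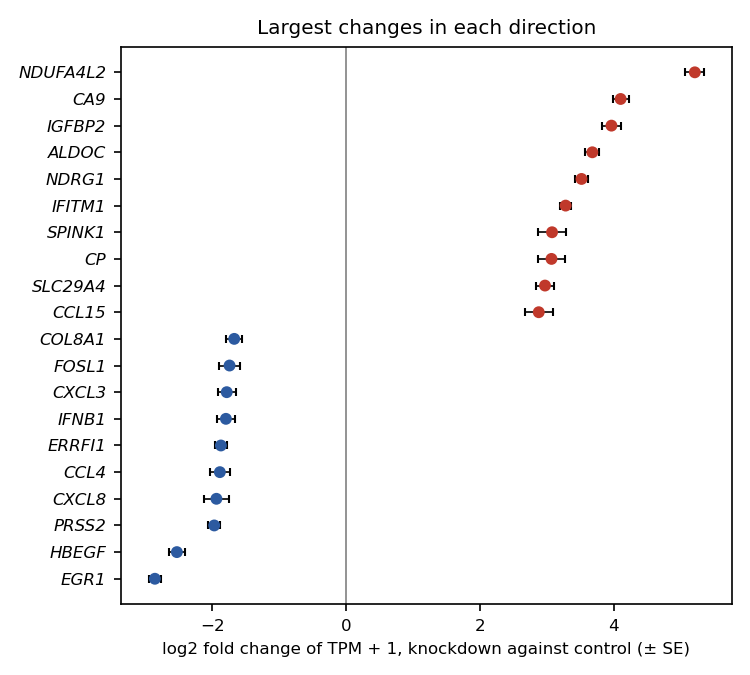
Log2 fold change of TPM + 1 (horizontal axis, knockdown against control) of the 10 protein-coding genes with the largest rise (red) and the 10 with the largest fall (blue) under the naming rule. Bars show the SE of the limma fit. Values run from -2.86 (EGR1) to 5.22 (NDUFA4L2).

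Genes of DNA replication licensing and the G1/S transition fell together. All 28 called members of 30 measured fell, and 0 rose, with a median log2 fold change of -0.91 (camera adjusted p = 5.57e-15, but adjusted p = 0.283 with an estimated correlation). Adjusted over the list alone, 30 fell. The transcription factor E2F1 fell from 35.2 ± 2.29 to 13.3 ± 1.05 TPM. The replicative helicase factors CDC45 and MCM3 fell from 37.4 ± 1.87 to 13.7 ± 2.17 TPM and from 54.6 ± 6.96 to 23.8 ± 1.8 TPM. Cyclin E2 (CCNE2) fell from 5.41 ± 1.13 to 1.19 ± 0.159 TPM. GINS1 and GINS4, the 2 members that did not pass over all genes, had log2 fold changes of -0.26 and -0.45 and were chosen after their values were seen.

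Mitotic genes changed less. Among 24 measured G2/M and mitosis genes, 1 rose, 5 fell and 18 did not pass. Adjusted over the list alone, 1 rose and 4 fell. The median log2 fold change was -0.24 (camera adjusted p = 0.00826, but adjusted p = 0.574 with an estimated correlation, and fry adjusted p = 0.0847). The proliferation marker MKI67 fell from 26.2 ± 3.57 to 16.8 ± 1.77 TPM and the mitotic kinesin KIF23 from 35.7 ± 5.46 to 21.7 ± 1.39 TPM. Cyclin A2 (CCNA2) fell from 29.7 ± 6.97 to 18.6 ± 0.459 TPM, and KIF20A rose from 16.2 ± 1.16 to 21.0 ± 0.674 TPM. The calls of CCNA2 and KIF20A did not hold in every alternative. Mean log2 change in the G1/S list was lower than in the G2/M list by a difference of -0.65 (SE 0.07, 3 libraries per group).

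Genes of hypoxia and glycolysis rose: 19 of 23 measured rose, 1 fell and 3 did not pass, with the same counts adjusted over the list alone. The median log2 fold change was 0.64 (camera adjusted p = 1.33e-08, but adjusted p = 0.186 with an estimated correlation). Besides CA9 and NDRG1, the vasodilator peptide gene ADM rose from 4.36 ± 0.114 to 16.2 ± 0.718 TPM, and the glycolytic kinase PGK1 from 275 ± 31.4 to 700 ± 48 TPM. The member that fell was VEGFA, the angiogenic growth factor also induced by hypoxia, from 182 ± 14.4 to 128 ± 7 TPM, chosen after its values were seen. Of 26 nuclear-encoded oxidative phosphorylation genes, 7 rose, 2 fell and 17 did not pass (6 rose and 2 fell adjusted over the list alone). SDHA rose from 104 ± 2.09 to 150 ± 12.9 TPM, NDUFA1 rose from 430 ± 21.9 to 583 ± 29 TPM, and NDUFA4 fell from 48.3 ± 6.62 to 32.8 ± 0.937 TPM. As a group they did not pass (median log2 fold change 0.12, camera adjusted p = 0.14, and 0.786 with an estimated correlation), but passed without a filter (0.0496) and without control replicate 3 (0.0364).

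For 13 mitochondrial-encoded mRNAs, 0 rose, 2 fell and 11 did not pass (0 rose and 1 fell adjusted over the list alone). Their median log2 fold change was -0.18 (camera adjusted p = 0.111, and 0.674 with an estimated correlation), beside a mitochondrial share of TPM of 39.8% in control and 35.4% after knockdown. The 2 were MT-ND1 (log2 fold change -0.37) and MT-ATP8 (-0.36), which overlaps MT-ATP6, and neither call held in every alternative. The list passed without a filter (camera adjusted p = 0.0117) and without control replicate 3 (0.0339). The 21 cholesterol synthesis genes had 10 members that rose, 0 that fell and 11 that did not pass, with the same counts adjusted over the list alone. The median log2 fold change was 0.33 (camera adjusted p = 0.00176, but adjusted p = 0.375 with an estimated correlation). INSIG1, a sterol sensor, rose from 16.0 ± 2.74 to 42.3 ± 1.51 TPM and SREBF2, which drives the pathway, from 30.2 ± 0.675 to 46.0 ± 1.34 TPM.

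Among measured genes of intestinal differentiation, most rose in both lists examined. Only 12 of 20 goblet and secretory genes and 11 of 24 enterocyte genes passed the filter. AGR3, named below, reached 1 TPM only in the knockdown libraries. In the goblet and secretory list, 9 of 12 measured genes rose, 0 fell and 3 did not pass (10 rose adjusted over the list alone), with a median log2 fold change of 1.06 (camera adjusted p = 3.92e-06, but adjusted p = 0.151 with an estimated correlation). The mucin MUC1 rose from 19.4 ± 3.72 to 88.5 ± 6.25 TPM, the disulfide isomerase AGR3 from 0.337 ± 0.157 to 4.95 ± 0.999 TPM and the transcription factor CREB3L1 from 12.6 ± 1.32 to 32.4 ± 2.01 TPM. In the enterocyte list, 8 of 11 measured genes rose, 1 fell and 2 did not pass, with the same counts adjusted over the list alone. Its median log2 fold change was 1.30 (camera adjusted p = 6.9e-05, but adjusted p = 0.221 with an estimated correlation). CEACAM7 rose from 11.05 ± 1.45 to 57.4 ± 0.974 TPM and villin (VIL1), a microvillus protein, from 18.2 ± 1.1 to 61.9 ± 0.435 TPM. MUC13 rose from 35.1 ± 1.86 to 113 ± 1.12 TPM. KLF4, the member that fell, went from 20.4 ± 1.47 to 12.4 ± 1.08 TPM and was chosen after its values were seen.

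Junction genes moved in both directions: of 22 epithelial junction genes, 7 rose, 3 fell and 12 did not pass, also when adjusted over the list alone. The claudin CLDN3 rose from 32.2 ± 1.09 to 62.9 ± 5.42 TPM and the epithelial transcription factor ELF3 from 113 ± 12.1 to 221 ± 17.7 TPM. The group did not pass (median log2 fold change 0.06, camera adjusted p = 0.463, and 0.674 with an estimated correlation; fry adjusted p = 0.0458). Of 11 mesenchymal and EMT genes, 3 rose, 5 fell and 3 did not pass, also when adjusted over the list alone. The matrix gene TNC fell from 42.8 ± 2.73 to 15.6 ± 0.29 TPM and the urokinase receptor PLAUR from 178 ± 9.49 to 114 ± 4.35 TPM. This group did not pass (camera adjusted p = 0.314, and 0.574 with an estimated correlation; fry adjusted p = 0.00278). Among 15 Wnt target genes, 3 rose, 3 fell and 9 did not pass (3 rose and 4 fell adjusted over the list alone). MYC fell from 73.8 ± 2.22 to 38.8 ± 2.86 TPM and the Wnt antagonist DKK1 from 91.0 ± 10.5 to 36.5 ± 6.37 TPM, while SP5 rose from 2.71 ± 0.526 to 10.9 ± 2.18 TPM. Their median log2 fold change was -0.02, their mean 0.02, and camera gave an adjusted p of 0.908, and 0.949 with an estimated correlation. YAP/TEAD target genes fell: 9 of 15 fell, 1 rose and 5 did not pass, also when adjusted over the list alone. Their median log2 fold change was -0.40 (camera adjusted p = 0.000298, but adjusted p = 0.221 with an estimated correlation). AMOTL2 fell from 25.8 ± 0.455 to 11.3 ± 0.675 TPM, ASAP1 fell from 21.7 ± 2.26 to 9.68 ± 0.556 TPM, and GADD45B rose from 5.44 ± 1.31 to 13.7 ± 1.8 TPM.

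**Figure D3:**
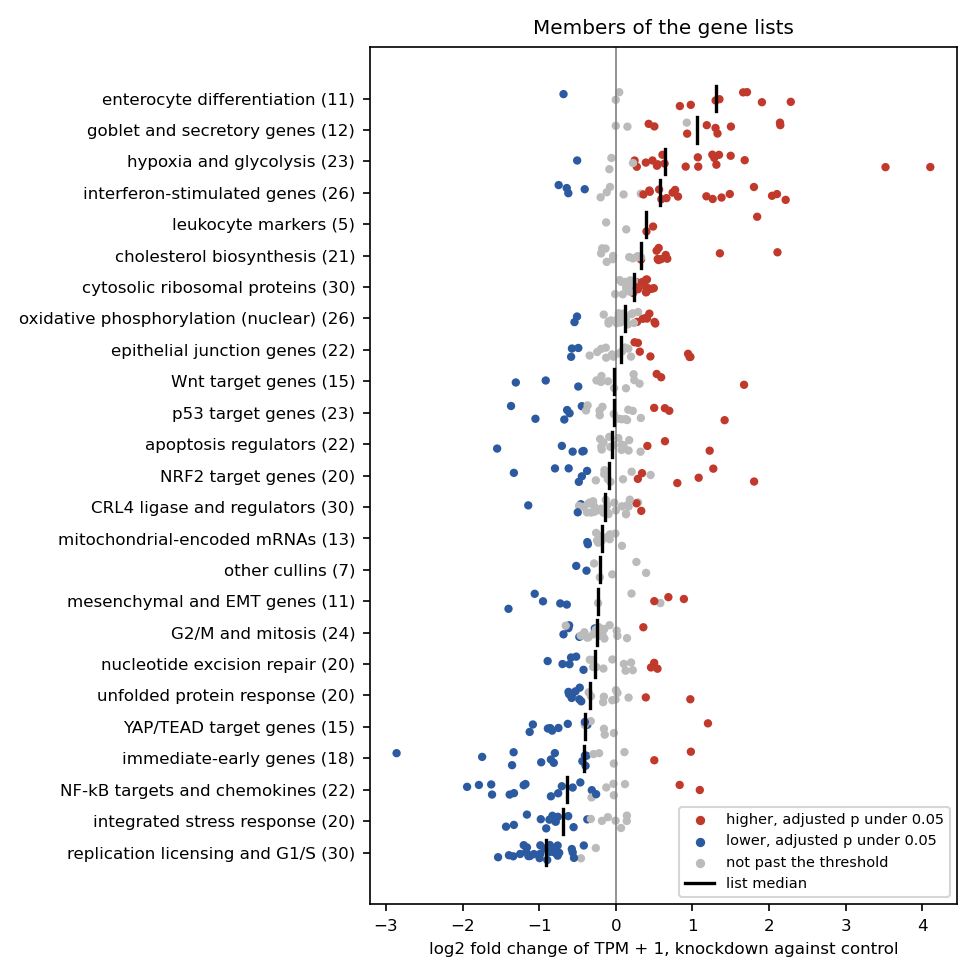
Log2 fold change of TPM + 1 (horizontal axis, knockdown against control) of each measured member of the 25 lists tested, with the number measured in parentheses and lists ordered by median. Points are genes coloured by their limma call and black lines are list medians, which run from -0.91 for replication licensing and G1/S to 1.30 for enterocyte differentiation.

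Of 22 measured NF-kB targets and chemokines, 15 fell, 2 rose and 5 did not pass (16 fell and 2 rose adjusted over the list alone), with a median log2 fold change of -0.63 (camera adjusted p = 4.9e-05, but adjusted p = 0.221 with an estimated correlation). CXCL2 fell from 50.1 ± 1.39 to 15.9 ± 3.01 TPM, TNFAIP3, an inhibitor of NF-kB, from 19.3 ± 1.14 to 7.98 ± 0.269 TPM and IL6 from 5.80 ± 0.946 to 1.20 ± 0.225 TPM. The 2 that rose, LCN2 (761 ± 20 to 1364 ± 168 TPM) and IL32 (28.3 ± 3.28 to 61.6 ± 6.32 TPM), were chosen after their values were seen. Of 26 interferon-stimulated genes, 17 rose, 4 fell and 5 did not pass, also when adjusted over the list alone. The median of the group was 0.58 on the log2 scale (camera adjusted p = 6.02e-05, but adjusted p = 0.375 with an estimated correlation). IFI27 rose from 176 ± 20.2 to 820 ± 86.3 TPM, IFI6 from 77.4 ± 4.4 to 274 ± 30 TPM and MX2, an antiviral GTPase, from 2.76 ± 0.192 to 14.5 ± 2.02 TPM. The 4 that fell, chosen after their values were seen, were the RNA sensors RIGI (log2 fold change -0.62) and IFIH1 (-0.64) and the antiviral genes IFIT2 (-0.75) and IFIT3 (-0.41), the last not called in every alternative. Of 18 immediate-early genes, 12 fell, 2 rose and 4 did not pass (13 fell and 2 rose adjusted over the list alone). At the level of the list, the median log2 fold change was -0.42 (camera adjusted p = 6.9e-05, but adjusted p = 0.221 with an estimated correlation). Besides EGR1 and FOSL1, the ERK phosphatase DUSP6 fell from 57.0 ± 6.52 to 21.6 ± 1.53 TPM and IER3 from 259 ± 26.4 to 131 ± 15.3 TPM. The 2 that rose were JUND (11.6 ± 0.766 to 24.3 ± 6.39 TPM) and NR4A1 (6.56 ± 1.09 to 9.69 ± 1.22 TPM), chosen after their values were seen, with NR4A1 not called in every alternative.

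Of 20 integrated stress response genes, 13 fell, 0 rose and 7 did not pass, also when adjusted over the list alone. The median across the list was -0.69 on the log2 scale (camera adjusted p = 1.87e-05, but adjusted p = 0.375 with an estimated correlation). PPP1R15A, a regulatory subunit of the eIF2alpha phosphatase, fell from 172 ± 8.2 to 63.2 ± 3.09 TPM. The amino acid transporter genes SLC7A11 and SLC3A2 fell from 19.98 ± 3.01 to 7.30 ± 0.505 TPM and from 346 ± 7.87 to 199 ± 7.68 TPM. Of 20 unfolded protein response genes, 9 fell, 2 rose and 9 did not pass (10 fell and 2 rose adjusted over the list alone). Their median log2 fold change was -0.34 (camera adjusted p = 0.0235, but adjusted p = 0.574 with an estimated correlation; fry adjusted p = 0.055). The chaperone HSPA5 fell from 573 ± 74.6 to 382 ± 3.81 TPM and HYOU1 from 232 ± 8.64 to 151 ± 7.25 TPM. The co-chaperone DNAJB9 rose from 8.10 ± 1.43 to 16.7 ± 0.286 TPM, as did HERPUD1 (log2 fold change 0.39), which was chosen after its values were seen and not called in every alternative. Without control replicate 3 the list did not pass (camera adjusted p = 0.0738).

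Of 23 p53 target genes, 4 rose, 6 fell and 13 did not pass, also when adjusted over the list alone. GDF15 fell from 201 ± 20.8 to 77.1 ± 2.23 TPM and TP53INP1 rose from 0.863 ± 0.121 to 3.99 ± 0.278 TPM. CDKN1A, which encodes p21, was at 67.4 ± 2.71 TPM in control and 58.2 ± 3.89 TPM after knockdown (limma adjusted p = 0.0943), and was chosen after its values were seen. The group did not pass (median log2 fold change -0.03, camera adjusted p = 0.578, and 0.819 with an estimated correlation). Of 20 nucleotide excision repair genes, 3 rose, 6 fell and 11 did not pass (3 rose and 9 fell adjusted over the list alone). LIG1, a DNA ligase, fell from 29.7 ± 0.9 to 19.2 ± 1.19 TPM and ERCC1 rose from 41.0 ± 2.29 to 60.4 ± 4.67 TPM. The group did not pass (median log2 fold change -0.27, camera adjusted p = 0.14, and 0.574 with an estimated correlation), but passed without a filter (0.0322). Of 22 apoptosis regulators, 3 rose, 5 fell and 14 did not pass, also when adjusted over the list alone. PMAIP1 fell from 39.0 ± 5.74 to 12.6 ± 0.125 TPM, while BMF rose from 12.4 ± 1.17 to 30.2 ± 1.07 TPM, both encoding pro-apoptotic BCL2-family proteins. The group did not pass (median log2 fold change -0.05, camera adjusted p = 0.578, and 0.887 with an estimated correlation). Of 20 NRF2 target genes, 6 rose, 6 fell and 8 did not pass (7 rose and 6 fell adjusted over the list alone). The aldo-keto reductase AKR1C3, which has close paralogs, rose from 13.4 ± 1.16 to 49.6 ± 4.85 TPM, while SLC7A11, also a member of this list, fell as given for the integrated stress response. The median log2 fold change was -0.09 and the mean 0.08, and camera gave an adjusted p of 0.911, and 0.963 with an estimated correlation.

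Of 30 cytosolic ribosomal protein genes, 15 rose, 0 fell and 15 did not pass (19 rose adjusted over the list alone). Their median log2 fold change was 0.24 (camera adjusted p = 0.000185, but adjusted p = 0.574 with an estimated correlation). RPS19 rose from 2086 ± 31.6 to 2891 ± 304 TPM and RPL38 from 1041 ± 78.7 to 1468 ± 106 TPM. With quantile normalization the list did not pass (median 0.04, camera adjusted p = 0.331), and the mitochondrial share of TPM moved with the groups, as given above. Markers of other cell types were mostly below the filter. Of 16 leukocyte markers, 5 were measured, of which 3 rose and 0 fell, also when adjusted over the list alone. CD68, a lysosomal protein also made outside leukocytes, rose from 5.73 ± 0.413 to 23.2 ± 1.94 TPM. CD14 and CORO1A, at 2.64 and 6.12 TPM after knockdown, were not called in every alternative. The leukocyte list did not pass (camera adjusted p = 0.0603, and 0.574 with an estimated correlation), but passed without control replicate 3 (0.0321), knockdown replicate 1 (0.0257) or knockdown replicate 2 (0.0409), and by fry (adjusted p = 0.00381). Of 12 fibroblast markers, 2 were measured, and COL1A1 rose from 2.04 ± 0.497 to 3.82 ± 0.276 TPM. Of 10 endothelial markers, 4 were measured: EGFL7 rose from 1.82 ± 0.681 to 9.86 ± 0.592 TPM, ENG rose from 10.1 ± 1.45 to 13.8 ± 1.29 TPM and ROBO4 fell from 3.57 ± 0.571 to 1.26 ± 0.39 TPM, with ENG not called in every alternative. Adjusted over the list alone, 1 fibroblast marker rose, and 3 endothelial markers rose and 1 fell.

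In all, camera called 13 of 25 lists, 6 higher and 7 lower, at the preset correlation of 0.01. Splits of the libraries that mix the groups gave 5 to 12 calls at that setting. With an estimated correlation camera called 0, with 5 at an unadjusted p below 0.05 (goblet and secretory, hypoxia and glycolysis, YAP/TEAD, NF-kB and enterocyte). The self-contained test fry called 14 lists, among them 11 of the 13.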

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

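Removal of the GC content and length trend and the KEGG test were chosen after seeing the data. CUL4A fell under every alternative run, by log2 changes from -1.45 to -1.16, and the 20 largest changes kept their direction and call in each of theirs. Requiring an absolute log2 fold change of at least 1 left 558 higher and 174 lower genes. Without a filter 1536 genes were lower, with 31500 genes tested in place of 13975, and with array weights 3857 were lower; the cause of the latter was not tested. Leaving out each library gave 1576 to 2715 higher and 1425 to 3130 lower genes, with fewer libraries in each fit: 1576 and 1729 higher without knockdown replicates 1 and 2, and 1425, 1547 and 1569 lower without control replicate 1 and knockdown replicates 2 and 3. Rescaling without mitochondrial-encoded and the 20 most abundant genes gave 2374 higher and 3490 lower and moved the median of all genes by -0.09. With an estimated correlation camera called 0 lists in place of 13, with 5 at an unadjusted p below 0.05 and 14 by fry. Over the other alternatives, lists called ranged from 12 to 17. The replicate numbers did not pair the libraries: residuals of same-numbered libraries correlated at -0.06, -0.03 and 0.03, and the fit with a replicate block called 2553 higher and 2219 lower genes. Of 153 genes followed, 14 lost their call in at least 1 alternative (NAE1, DCAF7, CUL2, CCNA2, KIF20A, MT-ND1, MT-ATP8, CD14, CORO1A, ENG, AMBRA1, IFIT3, NR4A1 and HERPUD1), 4 gained one (CUL4B, CDKN1A, GINS1 and GINS4) and 0 reversed. Count-based alternatives were not run because the table holds TPM only, and with depth unknown the precision of low genes cannot be stated.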

Other observations

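Pathways assigned in the deposited table were tested after the data were seen, and the genes named in this paragraph and the next were chosen after their values were seen. Camera called 21 of 320 KEGG pathways higher and 17 lower, and 0 with an estimated correlation, with 2 at an unadjusted p below 0.05. Ribosome biogenesis genes fell, with 40 of 67 lower and 2 higher (median log2 fold change -0.43, camera adjusted p = 8.73e-07, but adjusted p = 0.991 with an estimated correlation). The nucleolar proteins NOP56 and TCOF1 fell from 315 ± 6.38 to 154 ± 15.3 TPM and from 19.3 ± 1.02 to 10.9 ± 0.527 TPM, and the pseudouridine synthase DKC1 from 112 ± 14.2 to 50.4 ± 2.93 TPM. Nucleocytoplasmic transport genes also fell, with 46 of 92 lower and 0 higher (median -0.35, camera adjusted p = 8.73e-07, but adjusted p = 0.991 with an estimated correlation), among them the nuclear pore gene NUP153, from 13.9 ± 1.4 to 7.64 ± 0.475 TPM. Homologous recombination genes fell in 19 of 35 cases and rose in 2 (median -0.42, camera adjusted p = 0.00152, but adjusted p = 0.991 with an estimated correlation). The KEGG sets for nucleotide excision repair and p53 signaling were also called lower, unlike the fixed lists for each. Both share genes with results given above, so they are not wholly separate from them. The nucleotide excision repair set holds CUL4A itself, its member with the smallest p, and PCNA of the fixed G1/S list. The p53 signaling set holds CCNE2, CCNE1 and RRM2 of that G1/S list, among its members with the smallest p. In nucleotide excision repair 19 of 54 genes fell and 4 rose. Its median was -0.24 (camera adjusted p = 0.0195, but 0.991 with an estimated correlation). In p53 signaling 24 of 62 genes fell and 8 rose. Its median was -0.26 (camera adjusted p = 0.0175, but 0.991 with an estimated correlation). The KEGG set for oxidative phosphorylation was called higher, also unlike its fixed list. In this set 36 of 119 genes rose and 8 fell, and NDUFA4L2 had the smallest p. The median of the set was 0.14 (camera adjusted p = 0.0351, but 0.991 with an estimated correlation). Steroid hormone synthesis genes rose in 12 of 25 cases and fell in 0 (median 0.33, camera adjusted p = 0.00715, but adjusted p = 0.991 with an estimated correlation). Members with the smallest p included AKR1C3, AKR1C1 and AKR1C2, paralogs that may not be fully separated. AKR1C1, UGT1A6 and HSD11B1L were also among those of the KEGG set for xenobiotic metabolism, likewise called higher, so the call is not specific to steroid hormones.

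Among interferon genes, which were not a fixed list and were not tested as a group, IFNL1 fell from 128 ± 11.4 to 51.1 ± 5.97 TPM, and the near-identical IFNL2 and IFNL3 from 69.5 ± 6.73 to 32.6 ± 3.22 TPM and from 64.5 ± 2.84 to 32.2 ± 3.27 TPM, beside the fall of IFNB1. IFNE fell from 2.22 ± 0.333 to 0.387 ± 0.15 TPM, and IFNL4, annotated as a polymorphic pseudogene, did not pass (log2 fold change -0.19, limma adjusted p = 0.496). All 5 metallothionein genes tested rose, also under each scaling tried, though family members share sequence: MT1G from 2.14 ± 0.121 to 18.4 ± 2.93 TPM, MT1X from 45.4 ± 7.29 to 163 ± 14.9 TPM, and MT2A from 205 ± 27.2 to 337 ± 34.4 TPM. The elastase inhibitor PI3, at 3051 ± 203 TPM in control, fell to 1069 ± 22.2 TPM. The trypsinogen PRSS1, which is similar to PRSS2, fell from 64.2 ± 2.68 to 19.7 ± 3.34 TPM. Among noncoding RNAs, H19 rose from 1.23 ± 0.583 to 33.4 ± 3.53 TPM and MIR210HG, the host of a hypoxia-induced microRNA, from 1.81 ± 0.612 to 25.1 ± 5.02 TPM.

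The test of cycling cells and the removal of the GC content and length trend were chosen after the result or the data were seen. The fall of replication licensing and G1/S genes was still there after removal of the trend with GC content and length (median -0.94) and after rescaling without mitochondrial-encoded and the 20 most abundant genes (median -1.04), which argues against either as its whole source. If a lower share of cycling cells alone lowered mitotic genes as much, the lists would fall alike. The mean change of the G1/S list minus that of the G2/M list was -0.65 (SE 0.07). Whether fewer cycling cells lower both lists alike was not tested, so this explanation is not excluded. Also open are a cell cycle phase shift, a culture density difference, an off-target or procedural effect of the knockdown and the loss of CUL4A itself. The labels separate none of these from the groups, for these genes or for any other change reported here.

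Long noncoding RNAs rose more often than they fell: 119 of 501 lincRNAs were higher and 40 lower (median log2 fold change 0.15), and 128 of 692 antisense RNAs were higher and 42 lower (median 0.13). The values argue against low abundance as its source: protein-coding sets matched on abundance had lower medians than both classes in at least 99.99% of 10000 draws. LincRNAs, which are annotated as intergenic, had a median above 99.99% of matched sets. Overlap with other genes was not measured and strand assignment is unknown, so reads from overlapping genes stay open for both classes. The draws treated genes as independent, so these shares make no allowance for genes that vary together. The lncRNA share of TPM was 1.22 ± 0.0843% in control and 1.28 ± 0.0539% after knockdown (exact permutation p = 0.4, smallest possible 0.1). The number of genes above 0 moved with the groups (23545 ± 449 and 24732 ± 320), and 92 sense intronic RNAs had a median of 0.01; a difference in RNA or library quality was not tested and stays open.

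The fall of EGR1, HBEGF and chemokine genes may reflect lower output of the ERK pathway. Of 8 measured ERK output genes, 4 fell (DUSP6, and DUSP4, EPHA2 and SPRY4, the last 3 chosen after their values were seen) and 0 rose, with a median log2 fold change of -0.57, which is not the majority past the threshold that the explanation asked for. By the count used for harvest, 7 of the 8 were lower by more than 2 standard errors. DUSP4 and DUSP6 are also in the immediate-early list, as are most of the harvest genes below, so these are not separate evidence from that list. Handling of the cells at harvest could also move early genes: of 6 stress-induced early genes, 5 were lower by more than 2 standard errors, while FOS, chosen after its values were seen, had a log2 fold change of 0.11 (SE 0.11). These explanations cannot be told apart, because the labels give neither harvest nor culture separately from the groups.

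With 3 against 3 libraries there are 10 splits, too few for a share under 0.05. The real split gave 5005 genes past the threshold, and the highest of the other splits 2 (1 of the 10 splits gave as many as the real one, the real one itself). Each other split mixes control and knockdown libraries, so any difference between the groups widens its residual spread and lowers its gene calls. These counts therefore cannot tell what separates the groups. For gene lists at the preset correlation, the real split gave 13 and the others from 5 to 12 (again 1 of 10). Lists were thus also called at this setting in every split that mixes the groups.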
